A study of Mus musculus with 66 samples.

How the data were processed

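Gene expression was measured on 66 Affymetrix mouse arrays of medial prefrontal cortex from male mice. The mice were 10 to 12 weeks old, and each array held RNA pooled from 4 to 5 animals, per the labels' protocols. Animals received saline or ethanol at 1.8 g/kg intraperitoneally, were restrained for 15 minutes, spent 10 minutes in a light-dark chamber, and were killed 4 hours after the injection. The inbred strains C57BL/6J and DBA/2J had 3 arrays per treatment. The BXD panel, a set of recombinant inbred strains bred from crosses of those progenitors, had 27 strains with 1 saline and 1 ethanol array each. The labels state that samples were assigned to processing batches at random, and the batch of a given array was not used here.

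The deposited values are log2 expression levels that the authors made with affy and RMA, per the submitters' processing notes; versions are not given in the sources used here. RMA subtracts background, equalises the distribution of values across arrays and summarises the probes of each probe set, so values are relative. Differences between arrays of a whole-transcriptome kind are reduced by this, but some remained in the deposited values. Array medians lay between 5.67 and 5.77 and array standard deviations (SD) between 2.06 and 2.17. The first principal component held 14.7% of the variance and had a Pearson correlation of -0.70 with the array SD. The highest correlation between any 2 arrays was 0.998 and no array was treated as a copy of another. For these arrays their number limits the precision. In the progenitor comparisons the P-values of single genes measure the spread between pools of animals. The BXD strains had 1 array per treatment, so there they measure strain differences in response together with the spread between pools.

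The table held 45037 probe sets. The platform annotation gave 34945 of them 1 gene symbol, 932 several symbols and 9160 none; symbols of 34741 were updated by Entrez identifier through a RefSeq table of assembly GRCm38.p6, used for names only. Probe sets whose mean lay below the 40th percentile (log2 5.11) were removed, 18015 in all. Each gene was then represented by its brightest probe set over the 66 arrays, which left 13196 genes. The filter used the mean over all arrays, so a group mean can lie below it. No detection calls were used here, and a difference against such a dim level has no exact size. The table held 0 AFFX control probe sets. Probe sets with several or no symbols entered no main test.

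Groups, tests, gene lists and alternatives were fixed before the data were examined, apart from the additions given below. Differences were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with the data.table package (version 1.17.8) for reading. A gene passed at a Benjamini-Hochberg adjusted p below 0.05, and adjusted p values below are limma's unless another tool is named. The BXD ethanol effect was fitted on the 54 BXD arrays with strain as a block and had 26 residual degrees of freedom. The progenitor comparisons shared 1 fit of 12 arrays with 8 residual degrees of freedom, and tested ethanol minus saline in each strain, their mean, the difference of the strains' responses, and DBA/2J minus C57BL/6J after saline and after ethanol. The BXD strain effect was a moderated F over 26 strain coefficients, given with the intraclass correlation of each strain's saline and ethanol arrays. The spread of the ethanol response was the ratio of the BXD residual variance to that of the progenitors, tested one-sided with an F test.

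Strain is a characteristic of the BXD samples and pairs the arrays. The check centred arrays on their treatment's mean and took the 200 genes with the largest mean absolute progenitor difference among those past the threshold in both progenitor comparisons. Each of the 27 saline arrays then correlated best with the ethanol array of its own strain, and each of the 27 ethanol arrays with the saline array of its own strain. Own-strain correlations ranged from 0.882 to 0.967 (median 0.932), against a median of -0.0481 and a maximum of 0.452 between strains. The permutation p over 100000 relabellings was 1e-05, the smallest they can give, and a relabelling matched at most 8 strains.

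Genes were tested in 28 lists of pathways, receptor families and cell type markers with camera at an inter-gene correlation preset to 0.01, adjusted over the lists within each comparison. An estimated correlation was the alternative, and no list of any comparison passed with it. Genes named in the text followed fixed rules. For the BXD ethanol effect these were the 12 largest differences in each direction past the threshold that moved alike in at least 20 of 27 strains. For each progenitor ethanol effect they were the 6 largest in each direction past the threshold with no overlap of ethanol and saline arrays within a strain, or the 5 with the smallest p where fewer than 3 passed. For the interaction they were the 10 smallest p past the threshold, or the 5 smallest p where none passed, and for the spread of the response the 6 highest ratios past the threshold. For the saline progenitor difference they were the 12 largest in each direction past the threshold in both comparisons. For the strain effect they were the 12 with the highest intraclass correlation. Up to 4 list members with the smallest p were named, and Gsk3b, Gabra2, Nnt, Glo1, Kcnj9, Fkbp5, Sgk1, Per1, Fos and Mbp were always reported; 1 further gene of that set is not analysed here. Other genes named in the text were chosen after their values were seen.

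The tests were checked on simulated data with the real means and residual SDs of the 13196 genes. The noise was normal and drawn independently for each gene, and 200 genes were changed per effect. Variation shared across genes, as on the first principal component of the real arrays, was not simulated. The recoveries and false calls therefore check the tests and are not the power or error rate in the real data. For the BXD ethanol effect limma recovered 98.5% of genes changed 1.2-fold, and it called 18 unchanged genes beside the 200 changed at 3 fold sizes. For the C57BL/6J ethanol effect it recovered 11.9% of genes changed 1.2-fold, 73.1% of those changed 1.5-fold and all 66 of those changed 2-fold, with 9 unchanged genes called. For the BXD strain effect all 200 genes with a strain SD of 3 residual SDs were recovered, with 10 others called. For the spread of the response the F test recovered 0% of 200 genes at a response SD of 3 residual SDs, 83% at 6 and 100% at 12, with 0, 11 and 13 others called.

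Alternatives were no filter or a filter at the 60th percentile, all probe sets, repeated quantile normalization, centring of each array on its median, a trended robust prior, array weights, the first residual principal component as a covariate, all 66 arrays in 1 fit, the replicate number as a block, a Wilcoxon signed-rank test, and each array or strain left out in turn. The component was taken from the residuals of the same fit, so it left the estimated differences unchanged and lowered the residual variance. A higher count with it is therefore partly built in and does not show effects that the main fit missed. Added after the data were seen were the list test on the interaction, list means per strain with permuted signs, the list tests under both scalings, the reading of Gabra2 by treatment, and a comparison of the BXD and progenitor effects over genes at an unadjusted p below 0.05. So were the midpoint reading of Gabra2 and the search for other genes like it. The splits of the progenitor arrays and the random pairings of BXD arrays for the strain effect were also added then.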

Results

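The data describe the medial prefrontal cortex 4 hours after saline or an ethanol dose of 1.8 g/kg, in animals that were also restrained and placed in a light-dark chamber. There were 3 saline and 3 ethanol arrays of C57BL/6J, 3 and 3 of DBA/2J, and 27 and 27 of the BXD strains derived from both. In total 13196 genes were compared as log2 expression levels, and each array stood for a pool of 4 to 5 mice.

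The first question was which transcripts changed with ethanol across the BXD panel. Npas4, an activity-induced transcription factor of neurons, rose from 6.65 ± 0.29 to 7.49 ± 0.36 (log2, SD, n = 27). The paired difference was 0.84 (SE 0.08, adjusted p = 1.7e-07), a 1.79-fold rise (95% interval 1.59 to 2.02), and 24 of 27 strains were higher after ethanol. It was the 1 gene of 13196 to pass. Of all 13196 genes, Npas4 included, 651 had an unadjusted p below 0.05, 178 higher and 473 lower, where 660 are expected with no effect. A Wilcoxon signed-rank test over the 27 strain differences also called 1 gene, with Npas4 at an adjusted p of 0.00275. The count was 14, 5 higher and 9 lower, with the first residual principal component as a covariate, and 2 with all probe sets, repeated quantile normalization, array weights or all 66 arrays in 1 fit. It was 4 without BXD21, 3 without BXD32 and 2 without BXD01, BXD02, BXD23 or BXD27. The residual component came from the same fit and left the Npas4 difference at 0.84, so its count of 14 is partly built in.

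Several relatives of Npas4 among the immediate early genes, which neurons switch on shortly after stimulation, had higher means after ethanol. Of 26 measured members, 1 passed over all genes; adjusted over the list alone 12 were higher and 5 lower. Fos differed by 0.46 (SE 0.10) with 21 strains higher, and Egr2 by 0.41 (SE 0.10) with 20 higher, at adjusted p values over all genes of 0.115 and 0.211. Jun differed by 0.18 (SE 0.05). Arc, whose protein acts at synapses, differed by 0.45 (SE 0.12) with 22 of 27 strains higher. The members lower over the list alone were Bdnf, -0.14 (SE 0.04), a neurotrophin, Nptx2, -0.25 (SE 0.09), a synaptic pentraxin, Rgs2, Inhba and Gadd45b. The list as a whole moved up in the camera test (adjusted p = 1.89e-08), which was lost at adjusted p = 0.3 with an estimated correlation. The mean of the list rose in 19 of 27 strains, by 0.10 (SD 0.18), with a permutation p of 0.00886 and 0.223 after adjustment over the 28 lists, a test chosen after seeing the data. Both list tests include Npas4 itself and were not run without it. The median member differed by 0.06, with 18 of 26 positive and 8 negative.

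**Figure D1:**
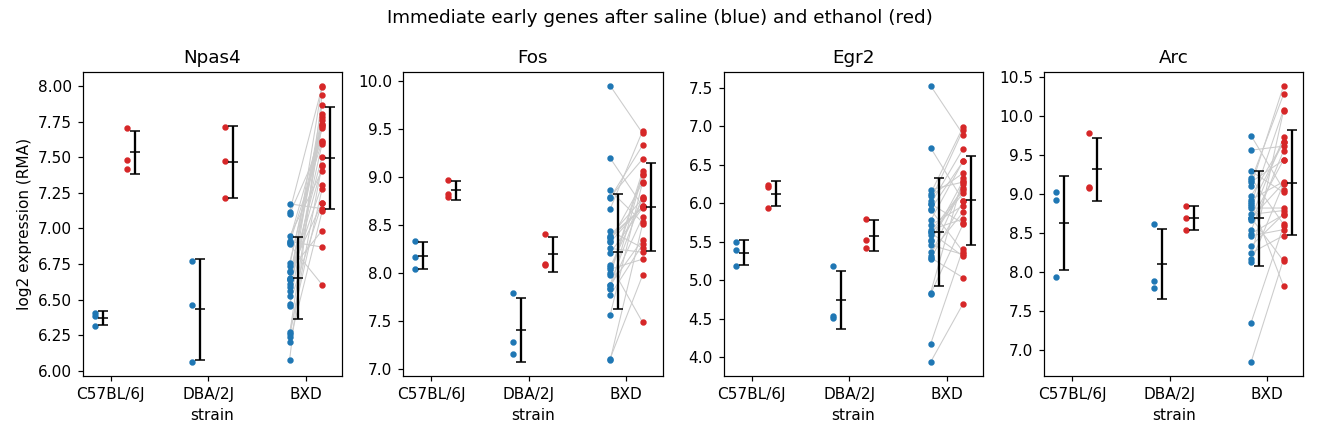
Log2 expression of Npas4, Fos, Egr2 and Arc on each array, by strain, after saline (blue) and ethanol (red). Black bars give the mean and SD, and grey lines join the saline and ethanol arrays of each of the 27 BXD strains; 24 of the 27 strains were higher for Npas4 and 21 for Fos.

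Glucocorticoid-responsive genes, induced by stress hormones in many tissues, also shifted up in camera (adjusted p = 2.48e-05; adjusted p = 0.417 with an estimated correlation). Of 23 members 0 passed over all genes by limma and 3 had an unadjusted p below 0.05. A positive difference was found for 19, and adjusted over the list alone 2 were higher. The mean of the list was higher in 15 of 27 strains (permutation p = 0.0971, adjusted p = 0.302). The 2 members higher over the list alone were Dusp1, a phosphatase of MAP kinases, 0.28 (SE 0.06), and Fkbp5, a co-chaperone of the glucocorticoid receptor, 0.16 (SE 0.05, 19 of 27 strains higher). Sgk1 and Per1 had differences of 0.00 (SE 0.04) and -0.01 (SE 0.06).

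Microglia markers shifted down (adjusted p = 9.45e-04; adjusted p = 0.457 with an estimated correlation). Of 15 measured members 14 had a negative difference, among them Aif1, -0.11 (SE 0.05), and Tyrobp, -0.09 (SE 0.04), but 0 passed in limma over all genes or adjusted over the list alone, and 6 had an unadjusted p below 0.05. The mean of the list was lower in 16 of 27 strains (permutation p = 0.0183, adjusted p = 0.223). The direction was not particular to microglia, and the median difference of all 13196 genes was -0.01. A negative difference was found for 16 of 17 endothelial and pericyte markers and 11 of 12 meningeal and fibroblast markers, lists that did not pass. Astrocyte markers had 8 positive and 8 negative. Transcripts of cytosolic heat shock proteins shifted down (camera adjusted p = 0.00589, and 0.457 with an estimated correlation). Hspb1, a small heat shock protein, had a difference of -0.20 (SE 0.05), lower in 20 of 27 strains, and was the 1 of 17 members lower adjusted over the list alone; 0 passed in limma over all genes and 2 had an unadjusted p below 0.05. The mean of this list of transcripts was lower in 20 of 27 strains (permutation p = 0.0239, adjusted p = 0.223). The remaining lists did not pass, with adjusted p values from 0.0534 for endothelial and pericyte markers to 0.904 for astrocyte markers. Among them, myelin markers were at 0.678, GABA-A receptor subunits at 0.0705, and ethanol and aldehyde metabolism genes at 0.882. The median, mean and direction of the test differed in sign for 7 of these lists: clock genes, myelin markers, oligodendrocyte precursor markers, inhibitory neuron markers, glutamate receptor subunits, GSK3 and Wnt signalling genes, and cholesterol synthesis genes. For clock genes the median was 0.00, the mean -0.01 and the test pointed up. In the other comparisons only lists that did not pass showed such a mismatch. Camera sets a list against the other genes, so in the BXD panel, where the median gene was at -0.01, a list near 0 can point up. Of the genes always reported, Gsk3b (0.02, SE 0.04), Gabra2 (0.05, SE 0.05), Nnt (0.00, SE 0.03), Glo1 (-0.03, SE 0.04), Kcnj9 (-0.02, SE 0.04) and Mbp (-0.02, SE 0.04) differed by about their standard error or less.

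The progenitors addressed the same question in inbred mice with 3 pools per treatment. In C57BL/6J Npas4 rose from 6.37 ± 0.05 to 7.53 ± 0.15 (SD, n = 3), a difference of 1.17 (SE 0.15, adjusted p = 0.0141), and was the 1 gene to pass; 657 had an unadjusted p below 0.05. Leaving out saline C57BL/6J replicate 1, 2 or 3 gave Npas4 an adjusted p of 0.0576, 0.183 or 0.118, leaving out ethanol replicate 1, 2 or 3 gave 0.0308, 0.06 or 0.184, and a fit of all 66 arrays gave 0.168. With the replicate number as a block it was 0.0584. Under the other filters, scalings and models it stayed below 0.05, from 0.00298 with array weights to 0.0231 with all probe sets. The next smallest p values, which did not pass, belonged to Pkp2, a desmosomal protein (0.54, SE 0.10), Egr2 (0.77, SE 0.16), Tox (-0.44, SE 0.09) and Fos (0.68, SE 0.14). In DBA/2J 0 genes passed in limma and 1643 had an unadjusted p below 0.05, of which 1092 were higher. The smallest adjusted p, 0.0557, was shared by Npas4 (6.43 ± 0.36 to 7.47 ± 0.25, SD, n = 3; difference 1.04, SE 0.15), Cth, an enzyme of cysteine synthesis (0.91, SE 0.14, from a dim saline mean of 4.92), and Dctn6, a dynactin subunit (0.87, SE 0.14). Fam174a (0.53, SE 0.09) and Gm10421 (0.40, SE 0.07) followed and did not pass. The DBA/2J adjusted p of Npas4 ranged from 0.00292 to 0.194 over the alternatives. It was above 0.05 with no filter (0.0563), all probe sets (0.0897), repeated quantile normalization (0.0556) and the replicate number as a block (0.194). The same held without saline replicate 1 (0.177) or 2 (0.0615), and without ethanol replicate 1 (0.111) or 2 (0.155). It was below 0.05 with the 60th percentile filter (0.0303), median centring (0.0475), a trended robust prior (0.0139), array weights (0.00658), the first residual principal component (0.00548) and all 66 arrays in 1 fit (0.0461), and without saline replicate 3 (0.00292) or ethanol replicate 3 (0.0353). In the DBA/2J ethanol effect the count depended on the model: 22 genes passed with a trended robust prior, 30 with all 66 arrays in 1 fit and 242 with the first residual principal component as a covariate. That component came from the residuals of the same fit and left the Npas4 difference at 1.04, so the count of 242 is partly built in.

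Averaged over both progenitors, 6 genes passed, 5 higher and 1 lower, and 1166 had an unadjusted p below 0.05. The count was 23, 22 of them higher, with the first residual principal component and 3 with all 66 arrays in 1 fit. Npas4 rose by 1.10 (SE 0.11, adjusted p = 3.15e-04), Egr2 by 0.80 (SE 0.11, adjusted p = 0.0107) and Fos by 0.73 (SE 0.10, adjusted p = 0.0107). The saline DBA/2J mean of Egr2, 4.74, lay below the level of log2 5.11 at which dim probe sets were removed, so the size of its rise is not exact. Pkp2 rose by 0.50 (SE 0.07), and Aass, an enzyme of lysine degradation, by 0.36 (SE 0.06). Tox, a nuclear protein, fell by 0.44 (SE 0.06). In camera the immediate early genes moved up (adjusted p = 4.13e-10; adjusted p = 0.322 with an estimated correlation), with 3 of 26 higher over all genes and 10 adjusted over the list alone. The glucocorticoid-responsive genes moved up too (adjusted p = 6.35e-04; adjusted p = 0.455 with an estimated correlation). By limma 0 of their 23 members passed over all genes, 5 had an unadjusted p below 0.05, and 4 were higher adjusted over the list alone: Fkbp5, 0.33 (SE 0.06), Dusp1, 0.34 (SE 0.08), Sult1a1, 0.27 (SE 0.07), and Tsc22d3, 0.29 (SE 0.09).

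Within C57BL/6J 7 lists passed in camera with the preset correlation. Immediate early genes moved up at adjusted p = 9.5e-06, and adjusted over the list alone 5 were higher. Glucocorticoid-responsive genes moved up at adjusted p = 8.62e-05, with 4 higher adjusted over the list alone. Meningeal and fibroblast markers moved up at adjusted p = 2.2e-04, led by Ogn (0.24, SE 0.09) and Slc6a20a (0.32, SE 0.13), with 0 of 12 passing in limma over all genes or adjusted over the list alone and 3 at an unadjusted p below 0.05. Innate immune and interferon genes moved up at adjusted p = 0.0149, with Cd14, a co-receptor for bacterial lipopolysaccharide (0.32, SE 0.09), higher adjusted over the list alone; the list was at 0.086 after repeated quantile normalization. Myelin and oligodendrocyte markers moved down at adjusted p = 0.00116, led by Mobp (-0.35, SE 0.10) and Gpr37 (-0.33, SE 0.10), with 4 of 19 at an unadjusted p below 0.05. Cholesterol synthesis genes moved down at adjusted p = 0.00189, led by Fdps (-0.25, SE 0.07), the 1 of 18 at an unadjusted p below 0.05, and Idi1 (-0.18, SE 0.09). Heat shock protein genes moved down at adjusted p = 0.0149, led by Chordc1 (-0.25, SE 0.09), the 1 of 17 at an unadjusted p below 0.05. In the myelin, cholesterol and heat shock lists 0 members passed in limma over all genes or adjusted over the list alone. For all 7 the result was adjusted p = 0.322 with an estimated correlation. In DBA/2J the immediate early genes were the 1 list to pass, moving up at adjusted p = 4.38e-06, and 7 were higher adjusted over the list alone, among them Egr1 (0.42, SE 0.09). That list was at adjusted p = 0.764 with an estimated correlation.

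Whether the progenitors responded differently to ethanol was tested as an interaction, and 0 genes passed in limma (smallest adjusted p 0.556; 1097 at an unadjusted p below 0.05). The smallest p values belonged to Mpzl2 (-0.93, SE 0.17, with group means of 4.85 to 5.42 near the dim level), Gsdmcl2 (-0.53, SE 0.10), Piga, an enzyme of membrane anchor synthesis (0.80, SE 0.16), Scyl2 (-0.48, SE 0.10) and 4930447M23Rik (0.66, SE 0.14), none of which passed. Npas4 passed in C57BL/6J and, in the shared fit of 12 arrays, not in DBA/2J, which is not shown to be a difference between them: its interaction was -0.13 (SE 0.21, adjusted p = 0.884). Fos passed in neither strain alone (adjusted p = 0.498 in C57BL/6J and 0.0842 in DBA/2J), and its interaction was 0.10 (SE 0.20).

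The BXD and progenitor effects, which share no arrays, correlated at 0.273 across genes, where genes are not independent replicates. Of 99 random sign flips of whole strains, 8 gave a correlation as large in size, between -0.304 and 0.391. Over all genes 58% had the same sign in the panel and the progenitors, within the 39.8% to 62.4% of the flips. Of the 651 genes at an unadjusted p below 0.05 in the BXD panel, a choice made after seeing the data, 466 (71.6%) had the same sign in the progenitors, within the 25.8% to 79.9% of the flips. Npas4, the 1 gene past the threshold in the panel, had the same sign.

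The next comparison asked how the progenitors differ without ethanol. DBA/2J and C57BL/6J differed in 1365 genes after saline, 537 higher and 828 lower in DBA/2J, and 3327 had an unadjusted p below 0.05. The count fell to 848 without saline C57BL/6J replicate 1 and to 902 without saline DBA/2J replicate 1. The latter array had the lowest SD of log2 values of the 12 progenitor arrays, 2.07, against 2.13 for both other saline DBA/2J arrays, and the highest score of all 66 on the first principal component (19.6), and it enters the DBA/2J ethanol effect too. After ethanol they differed in 954 genes, 573 higher and 381 lower. The balance of directions moved with the scaling: for saline DBA/2J against C57BL/6J, centring each array on its median gave 355 higher and 1013 lower, and for ethanol DBA/2J against C57BL/6J repeated quantile normalization gave 479 higher and 456 lower. Without ethanol DBA/2J replicate 3 the ethanol comparison gave 333 higher and 307 lower. In both comparisons 596 genes passed with the same sign, 297 higher and 299 lower in DBA/2J, and 0 passed with opposite signs. Of these, 88 differed at least 2-fold in both, 38 higher and 50 lower.

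The largest saline differences in favour of DBA/2J were those of Cap1, an actin-binding protein, at 3.39 (SE 0.15; 7.50 ± 0.41 in C57BL/6J and 10.90 ± 0.03 in DBA/2J, SD, n = 3), Gnb1, a G protein subunit, at 3.36 (SE 0.17), Pdxdc1 at 3.36 (SE 0.16), Rbm45 at 2.88 and Tmem87a at 2.57. Sstr1, a somatostatin receptor, followed at 2.53, Stab2 at 2.33, Serpina1b at 2.06, Hspa13 at 2.03, Wwox at 1.85 and Wdfy1 at 1.83. Kcnj9, a subunit of G protein-gated potassium channels, was higher by 2.14 (SE 0.12, adjusted p = 4.17e-09). Lower in DBA/2J were Prune2 at -5.04 (SE 0.23; 10.29 ± 0.25 in C57BL/6J and 5.26 ± 0.44 in DBA/2J, SD, n = 3), the long noncoding RNA Snhg14 at -4.30 (SE 0.24), Tmem267 at -4.04, Gm13306 at -3.78, Rpgrip1 at -3.25 and Pttg1 at -3.19. Acer3, a ceramidase, followed at -2.91, Sox11, a developmental transcription factor, at -2.87, Etnppl at -2.56, Gm26782 at -2.47, 2010315B03Rik at -2.44 and Sbsn at -2.41. For some of these genes the lower strain had a saline mean below log2 5.11, the level at which dim probe sets were removed. In C57BL/6J these were Sstr1 (4.50), Stab2 (4.88) and Serpina1b (4.67), and in DBA/2J Tmem267 (3.99), Gm13306 (4.72), Acer3 (4.30), Gm26782 (4.80) and 2010315B03Rik (4.34). Pdxdc1 in C57BL/6J (5.22) and Prune2 (5.26) and Etnppl (5.19) in DBA/2J lay just above it. Such levels were not shown to be above background, so these differences give a direction but no exact size or order. Some of these genes had more than 1 detected probe set. All of them had the sign given here for Cap1, Gnb1, Serpina1b, Wwox, Wdfy1, Pttg1 and Sbsn. For the others this held for 1 of 3 in Prune2, 1 of 3 in Pdxdc1, 2 of 4 in Hspa13, 3 of 4 in Kcnj9 and 4 of 5 in Sox11.

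**Figure D2:**
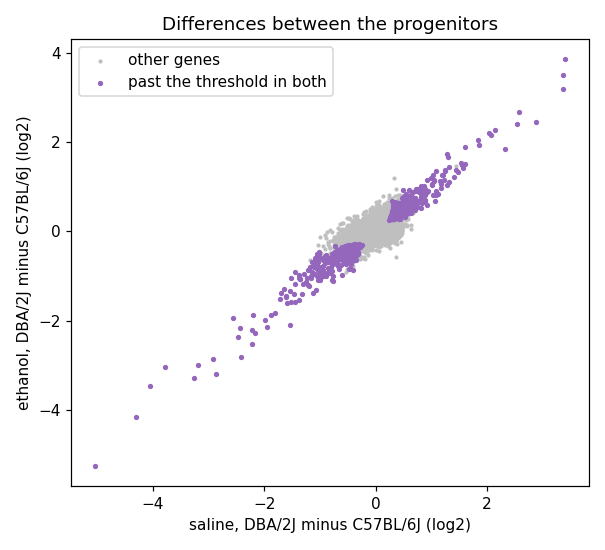
DBA/2J minus C57BL/6J for each of 13196 genes after saline (horizontal axis) and after ethanol (vertical axis), both log2. Purple points are the 596 genes past the threshold with the same sign in both, and grey points are the others; Prune2 lies at the lower left (-5.04 after saline) and Cap1 at the upper right (3.39).

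Myelin and oligodendrocyte markers were lower in saline DBA/2J. Of 19 members 11 were lower over all genes and 13 adjusted over the list alone, led by Mal, -1.36 (SE 0.10), Mobp, -0.94 (SE 0.10), Tspan2, -0.77 (SE 0.10), and Mbp, -0.71 (SE 0.10), which encode myelin membrane proteins. Camera gave adjusted p = 3.19e-11, and adjusted p = 0.159 with an estimated correlation. After ethanol Mal was still lower by -1.06 (adjusted p = 3.93e-06), while Mbp, at -0.34, had an adjusted p of 0.0631. Heat shock protein genes were lower as a list (camera adjusted p = 0.00369, and 0.348 with an estimated correlation). Of 17 members 4 were lower over all genes and 6 adjusted over the list alone. These included Hspa1b at -1.08 (SE 0.13) and Hspa1a at -0.69 (SE 0.15), near-identical inducible chaperones whose probe sets cannot be taken as independent.

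Ethanol and aldehyde metabolism genes were lower as a list (adjusted p = 0.0237; adjusted p = 0.322 with an estimated correlation), with 3 of 10 lower over all genes and 3 adjusted over the list alone: the aldehyde dehydrogenases Aldh9a1, -0.73 (SE 0.13), and Aldh1a1, -0.52 (SE 0.13), and catalase, Cat, -0.39 (SE 0.10). The endoplasmic reticulum chaperones were lower as a list (adjusted p = 0.0314; adjusted p = 0.322 with an estimated correlation), with 2 of 18 lower and 1 higher over all genes, and 9 lower and 2 higher adjusted over the list alone. That call was at 0.0596 after repeated quantile normalization. The immediate early genes were lower as a list (adjusted p = 0.0496; adjusted p = 0.725 with an estimated correlation), at 0.0596 after repeated quantile normalization, 0.0642 after median centring and 0.0945 without members shared with another list. Of 26 members 5 were lower and 2 higher over all genes, and 7 lower and 2 higher adjusted over the list alone, with Egr1 at -0.63 (SE 0.09), Fos at -0.77 (SE 0.14) and Nr4a2 at -0.56 (SE 0.13) lower and Btg2 at 0.57 (SE 0.13) higher.

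Lists that did not pass held single large differences. Microglia markers had an adjusted p of 0.0619, with 4 of 15 lower over all genes and 4 adjusted over the list alone, among them Fcrls at -1.33 (SE 0.11) and the complement genes C1qb at -0.98 (SE 0.12) and C1qc at -0.91 (SE 0.12). Grin2b, an NMDA receptor subunit, was lower by -1.12 (SE 0.13), and Kcnj10, a glial potassium channel, higher by 0.68 (SE 0.08). Csnk1e, a casein kinase, was higher by 0.73 (SE 0.10). Of 14 measured genes with known variants between these strains, 3 were higher and 1 lower: Kcnj9, Glo1 at 1.08 (SE 0.12), a detoxifying glyoxalase, and Gabra2 at 0.77 (SE 0.11), a GABA-A receptor subunit, were higher and Mpdz at -0.84 (SE 0.13) lower. Nnt, at 0.01 (SE 0.09), Gsk3b at 0.19 (SE 0.09), Fkbp5 at -0.08 (SE 0.09), Sgk1 at -0.05 (SE 0.10) and Per1 at 0.20 (SE 0.12) did not pass.

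The BXD panel showed how far levels differ among strains whatever the treatment. The strain effect passed for 2688 genes (20.4%; 4339 at an unadjusted p below 0.05), against 4695 with the first residual principal component and 4098 with all probe sets. The intraclass correlation of a strain's saline and ethanol arrays had a median of 0.184 over genes, and 119 genes reached at least 0.9. The highest belonged to Prune2 (0.992; strain means from 5.00 to 10.44), Pdxdc1 (0.991), Soga3 (0.988), Pttg1 (0.988), 4833420G17Rik (0.985), Rpgrip1 (0.985), Hspa13 (0.982), Wwox (0.981), Zc4h2 (0.98), Kcnj9 (0.978; strain means from 7.84 to 10.34), Krt12 (0.977) and Scg5 (0.976). For Prune2, Pdxdc1, Hspa13 and Kcnj9 not all detected probe sets had the same sign between the progenitors, as given above. An inherited DNA variant under a probe could also give a high intraclass correlation, and this was not tested apart from a difference in transcript level. Nnt differed among strains (intraclass correlation 0.925, adjusted p = 5.07e-12). For Npas4 the strain effect did not pass (adjusted p = 0.691).

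Most genes that separated the progenitors also differed among strains, while most genes with a strain effect did not pass in both progenitor comparisons. Of the 596 genes that differed in both progenitor comparisons, 544 (91.3%) had a strain effect, against 2144 of 12600 others (17.0%). The odds ratio was 51.0 (95% interval 38.2 to 69.4, Fisher's exact test, genes not being independent). It was 12.3 with the genes called in the saline comparison alone and 78.1 with all probe sets. The median intraclass correlation of the 596 genes was 0.762, against 0.17 for the others. Inherited DNA variants under probes could contribute to this overlap, which was not tested.

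Whether strains of the panel differed in their ethanol response was asked through the spread of the response. By the variance-ratio F test 0 genes passed (794 at an unadjusted p below 0.05, smallest adjusted p 0.575), and with limma's squeezed variances 0 passed (527 at an unadjusted p below 0.05). The median ratio of BXD to progenitor residual variance was 1.15, where the F distribution has a median of 1.06. With 8 residual degrees of freedom in the progenitors, the simulated recovery was 0% for a response SD of 3 residual SDs. The result of 0 genes therefore does not exclude strain differences of that size.

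**Figure D3:**
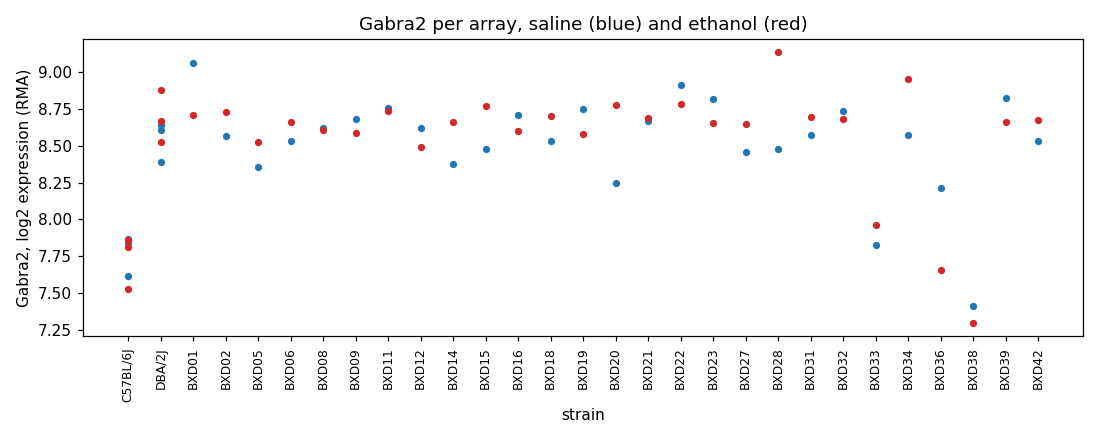
Log2 expression of Gabra2 on each array of C57BL/6J, DBA/2J and the 27 BXD strains, after saline (blue) and ethanol (red). BXD33, BXD36 and BXD38 have strain means of 7.90, 7.94 and 7.35, near the C57BL/6J mean of 7.75, and the DBA/2J mean is 8.62; the saline array of BXD36, at 8.22, lies nearer DBA/2J.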

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

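The list tests on the strain difference in ethanol response, the reading of Gabra2 at the midpoint of the progenitors, the search for other genes like it and the splits of the progenitor arrays were chosen only after results had been seen. This also holds for the random pairings of BXD arrays for the strain effect.

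Myelin and oligodendrocyte markers stood out because the list passed for the interaction with the preset correlation (camera adjusted p = 0.00762). With an estimated correlation camera gave adjusted p = 0.524, so a difference in response between the strains was not shown. The list mean changed by -0.13 in C57BL/6J and 0.08 in DBA/2J. Single BXD strains, with 1 array per treatment, ranged from -0.25 to 0.20. The interaction was positive for 16 of 19 members, among them Ugt8a at 0.48 (SE 0.19), Mbp at 0.37 (SE 0.15) and Mobp at 0.33 (SE 0.14); 0 passed in limma over all genes or adjusted over the list alone and 4 had an unadjusted p below 0.05. Meningeal and fibroblast markers stood out for the same reason and with the same limit (camera adjusted p = 0.00447, and 0.524 with an estimated correlation). Their list mean changed by 0.14 in C57BL/6J and -0.05 in DBA/2J, while single BXD strains ranged from -0.70 to 0.25. The interaction was negative for 11 of 12 members, among them Ogn at -0.31 (SE 0.13) and Slc6a20a at -0.39 (SE 0.19); 0 passed in limma over all genes or adjusted over the list alone and 1 had an unadjusted p below 0.05.

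For the ethanol effect averaged over the progenitors, 2 of 100 splits within strain, the real one included, gave at least the real 6 genes. The share is under 0.05. The highest other split gave 75, so the count of calls cannot exclude chance or sample structure as the source of the 6. That split set saline C57BL/6J replicate 1 with ethanol C57BL/6J replicates 1 and 3 against the rest of C57BL/6J and kept the DBA/2J arrays together by treatment, with the treatments exchanged. Calling several times the real count, it points to a structure of the samples, whose source was not identified: the split still held the DBA/2J arrays parted by treatment, and the other splits of the C57BL/6J arrays alone called at most 1 gene. For the interaction the real count was 0, which all 100 splits reach whatever the data (highest other 75), so the splits say nothing about chance there. In the BXD panel 4 of 100 label swaps, the real one included, gave at least 1 gene for ethanol (highest other 2). That share lies just under 0.05, so with 100 swaps the count alone does not exclude chance. For the strain effect 1 of 100 pairings of arrays gave as many as the real 2688 genes (highest other 13), so chance was excluded there. For single comparisons of 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real value and the highest other were 1 and 1 for C57BL/6J ethanol (2 of 10 as large), 0 and 0 for DBA/2J ethanol (10 of 10, which a real count of 0 fixes), 1365 and 0 for the saline difference (1 of 10), and 954 and 0 for the ethanol difference (1 of 10).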

How the results depend on the processing

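List means per strain, list tests under both scalings, Gabra2 by treatment and those on the interaction were chosen after seeing the data. Of the counts of genes, lists and paired arrays 181 alternatives lay within 1.5 times the main value and 47 did not; among single genes and lists 2235 kept direction and side of the threshold, 55 lost and 54 gained a call, and 63 changed sign. The cause was not tested unless stated. Higher counts with the first residual principal component are partly built in, because it lowers the residual variance and leaves the differences unchanged. The odds ratio of progenitor difference and strain effect, 51.0, was 12.3 with genes called after saline and 78.1 with all probe sets. The DBA/2J ethanol effect, 0 genes, gave 3 with the 60th percentile filter, 1 with median centring, 22 with trend and robust, 4 with arrayWeights, 242 with the first residual principal component and 30 with all 66 arrays in 1 fit. The BXD ethanol effect, 1 gene, gave 2 with all probe sets, 2 with quantile normalization, 2 with arrayWeights, 14 with the first residual principal component and 2 with all 66 arrays. The C57BL/6J ethanol effect, 1 gene, gave 2 with all probe sets, 0 with all 66 arrays and 0 with the replicate block. The progenitor ethanol effect, 6 genes, gave 23 with the first residual principal component and 3 with all 66 arrays. With all probe sets the BXD strain effect gave 4098 (4695 with the first residual principal component), saline DBA/2J against C57BL/6J 2124 and ethanol DBA/2J against C57BL/6J 1514, where more features were tested. The replicate numbers do not pair the progenitor arrays (correlations of same-numbered deviations 0.0818, -0.129 and -0.231 in C57BL/6J, 0.262, 0.117 and 0.0556 in DBA/2J); the block gave 5 genes for the progenitor effect, 1100 for saline and 763 for ethanol, and without pairing by strain the BXD count was 1. With an estimated correlation 0 lists passed in all 6 comparisons tested. BXD lists, 4, gave 7 with no filter and 0 as means per strain; DBA/2J lists, 1, gave 2 without shared members and 2 with quantile normalization; saline lists, 5, gave 3 with quantile normalization. Small differences that did not pass changed sign: under quantile normalization Gabra2 in C57BL/6J (0.00233), Glo1 (0.00563) and Gsk3b (0.00761) in the progenitor effect; under median centring Nnt after saline (-0.0291); with arrayWeights Sgk1 (-0.0131) and Per1 (0.0363) in BXD, Sgk1 in DBA/2J (-0.0493), Glo1 (0.0305), Mbp (-0.00313) and Gsk3b (0.0161) in the progenitor effect and Sgk1 after saline (0.00916). Leaving out 1 array gave 0 to 2 genes for C57BL/6J ethanol (0 without saline replicate 2 or 3 or ethanol replicate 2 or 3, 2 without ethanol replicate 1), 0 to 4 for DBA/2J (1 without saline replicate 2, 4 without saline replicate 3, 1 without ethanol replicate 3), 4 to 7 for the progenitors, 0 to 0 for the interaction, 848 to 1249 for the saline difference (848 without saline C57BL/6J replicate 1, 902 without saline DBA/2J replicate 1) and 640 to 870 for the ethanol difference, with fewer arrays in each. Leaving out 1 strain gave 1 to 4 genes for BXD ethanol (4 without BXD21, 3 without BXD32, 2 without BXD01, BXD02, BXD23 or BXD27) and 2217 to 2860 for the strain effect. Ranges that crossed 0 were, in C57BL/6J, Glo1 -0.00559 to 0.212 and Gabra2 -0.122 to 0.0602; in the progenitor effect Nnt -0.0568 to 0.0081, Glo1 -0.0542 to 0.0547, Mbp -0.0393 to 0.0573, Per1 -0.00349 to 0.111 and Gsk3b -0.0392 to 0.0293; in the interaction Fos -0.0211 to 0.294 and Kcnj9 -0.0134 to 0.257; after saline Sgk1 -0.126 to 0.0171 and Nnt -0.0243 to 0.0858; in DBA/2J Sgk1 -0.0245 to 0.12; after ethanol Gsk3b -0.043 to 0.0939; and in BXD Sgk1 -0.0179 to 0.0162, Nnt -0.00884 to 0.00835 and Per1 -0.0293 to 0.0201. The AFFX control covariate was not run, since the values used here held 0 such probe sets. The number of arrays limits the precision.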

Other observations

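The midpoint reading of Gabra2, its reading by treatment, the search for other genes like it, and the spread set beside the saline DBA/2J array were chosen only after results had been seen.

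Single clock genes differed between the strains after saline, in both directions. Of 18 clock genes 4 were higher and 3 lower in DBA/2J over all genes, and 6 higher and 4 lower adjusted over the list alone, with a list test that did not pass (adjusted p = 0.535). Per3 was higher by 0.87 (SE 0.09) and Usp2 by 0.41 (SE 0.10), while Per2, at -0.52 (SE 0.08), and Cry1, at -0.53 (SE 0.11), were lower. Of 23 glucocorticoid-responsive genes 3 were lower over all genes and 5 adjusted over the list alone (list adjusted p = 0.19), with Gjb6 at -0.56 (SE 0.09), Tsc22d3 at -0.45 (SE 0.13) and Klf9 at -0.33 (SE 0.08). Of 18 cholesterol synthesis genes 2 were lower over all genes and 2 adjusted over the list alone (list adjusted p = 0.838), among them Cyp51 at -0.53 (SE 0.09). Of 3246 detected probe sets without a gene symbol, 240 differed between the strains after saline and 214 after ethanol, while 0 passed in limma for the BXD ethanol effect (126 at an unadjusted p below 0.05).

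The 596 genes that separated the progenitors may in part reflect DNA variants under probes designed on C57BL/6J sequence. Of 295 such genes with a second detected probe set, 52.9% differed the same way on it at an unadjusted p below 0.05, against 16% of other genes. The share was 52.7% for genes lower in DBA/2J and 53.1% for genes higher. The explanation also predicted more genes lower than higher in DBA/2J. That part was not met, with 299 lower and 297 higher, though 50 were lower and 38 higher at 2-fold or more in both comparisons. The 297 higher genes lie opposite to the direction it predicts. The balance of directions moved with the scaling in each comparison, so the near-even counts do not decide about the cause. The share of 52.9% lay between the bounds set for the explanation and against it. Variants under probes and true differences in transcript level therefore cannot be told apart for the 596 genes as a set. A difference in expression between the strains stays open and was not tested by another assay.

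Low Gabra2 in some BXD strains may follow from a variant that arose in C57BL/6J after the oldest BXD strains were made, which is a hypothesis. None of the 21 strains numbered below 33 lay nearer the C57BL/6J than the DBA/2J mean (0 strains), against 3 of the 6 numbered from 33 on (Fisher's exact test, two-sided, p = 0.00684), and the other 2 detected Gabra2 probe sets gave the same 0 and 3. The count rests in part on BXD36, at 8.22 after saline, nearer DBA/2J, and 7.66 after ethanol: saline arrays alone gave 0 and 2 (p = 0.0427) and ethanol arrays alone 0 and 3. A bound set before the result was seen, 1 log2 unit from C57BL/6J, took in 18 of the 21 older strains and was void, because the progenitors differ by only 0.86. Among 310 genes examined, Wdfy1, in 1 later strain, was the 1 other gene at the C57BL/6J level in later strains only, while AI506816 was at the DBA/2J level in 3 later strains only, which this hypothesis does not predict, and a share of 0.222 of random choices of strains gave as many genes at the C57BL/6J level without Gabra2, so such variants in other genes stay open and ancestry was not tested here.

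More genes were lower than higher in DBA/2J after saline (60.7% lower) and the reverse held after ethanol (39.9% lower). The ethanol balance, 573 higher and 381 lower, came near even with repeated quantile normalization, at 479 higher and 456 lower, and without ethanol DBA/2J replicate 3, at 333 and 307. One candidate explanation is saline DBA/2J replicate 1, with the lowest SD of the 12 progenitor arrays (2.07): without it 902 genes passed and 56.3% were lower, while leaving out each of the 5 other saline arrays gave 61.3% to 67.7%. The value stayed on the side set against this explanation, but by less than the spread of the other 5 values (SD 2.6), so the test does not decide. A difference between the strains in their response to ethanol stays open, and its interaction test called 0 genes in limma (1097 at an unadjusted p below 0.05).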
